A study of Arabidopsis thaliana with 12 samples.

How the data were processed

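Total RNA of untreated Arabidopsis thaliana rosettes was hybridized to Affymetrix ATH1 arrays, on which each probe set (a group of short oligonucleotides) is designed to measure a transcript. Per the labels, the plants were 3 weeks old and were grown at 22 °C with 14 h of light, and 15 µg of total RNA was labelled per array. The 12 arrays fell into 4 genotypes of 3 arrays each, taken from the genotype and replicate number in the sample labels: the wild-type accession Col-0, the mutants pmr5 and pmr6, and the double mutant pmr5 pmr6. The labels call the replicates biological without saying how plants were pooled, so p-values measure the spread between these samples.

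The deposited value table holds 1 linear intensity per probe set and array for 22810 rows. The authors scaled the arrays to a common level, as read from the values: the mean intensity after leaving out the highest and lowest 2% of rows was 500 or 500.1 on every array. The software that turned the probe signals into intensities is not given in the sources used here. The table has no detection calls, so whether a dim probe set was detected could be judged only by its intensity level. Median intensities ran from 168 to 190 between arrays and array medians differed by at most 0.15 on the log2 scale, which by the rule fixed beforehand called for no further normalization.

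The headers of the per-array instrument records give a hybridization time and a fluidics module. Arrays whose successive times lay at most 30 minutes apart were taken as 1 hybridization run. This gave 3 runs of 4 arrays, with 1 run on the first day and 2 on the second. Each run held 1 array of each genotype, and the replicate number in the labels is the number of the run. In all 3 runs Col-0 was on fluidics module 1, pmr5 on module 2, pmr6 on module 3 and pmr5 pmr6 on module 4. Fluidics module and genotype therefore cannot be told apart in these arrays. The record of pmr5 pmr6 replicate 2 lists a staining step stopped by the operator, and the scan part of the record of pmr6 replicate 2 is empty.

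Intensities were turned to log2(intensity + 28), where the pseudocount of 28 is the 20th percentile of the table, so fold changes are on that scale and understate the change of dim probe sets. The 64 rows with AFFX (control) identifiers and then the dimmest 25% of rows by mean were left out, which kept 17059 probe sets. A linear model with 4 genotype means was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with an intensity trend), with 8 residual and 12 prior degrees of freedom. The 7 contrasts were each mutant against Col-0, the double mutant against each single mutant, pmr6 against pmr5, and the interaction (the double-mutant log2 change minus the sum of the single-mutant changes). A probe set was called at a Benjamini-Hochberg adjusted p under 0.05. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

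The fit was tested on simulated data with the real means and spreads and 200 changed probe sets among 17059. For pmr5 against Col-0 it recovered 26.4% of changes of 0.5 log2, 68.8% of changes of 1 log2 and 93.8% of changes of 2 log2. The shares were 27%, 64.8% and 94.4% for pmr6 against Col-0, and 32.4%, 72.7% and 97% for the double mutant. A further simulation changed 200 probe sets of each intensity level by 1 log2. More probe sets changed there, so its shares cannot be set beside those above, and neither gives the recovery at the real number of changes. Comparisons that share the Col-0 arrays were set beside 100 simulations of unchanged mutants. There all arrays, Col-0 included, were drawn anew around the Col-0 means with independent noise of the fitted spread.

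Row identifiers were checked before genes were to be named. A probe annotation listed 14016 of the 22810 identifiers, 13513 of them with 1 gene symbol and 503 with several, and did not list 8794. The check used 139 pairs of rows assigned to the same gene, rows assigned to 43 plastid photosynthesis genes, and rows with identifiers of spike-in controls, which are bacterial or phage transcripts added in known amounts. The identifiers did not track the values, as the report describes, so no row was assigned a gene and gene order was not used to restore names. For that reason the planned reports on the PMR5 and PMR6 transcripts, on named genes, on the 27 gene lists and on cell type markers were not made. The annotation listed 81 of the 460 genes of those lists, and neither of the 2 mutated genes. The rule fixed for named genes took, in each comparison with Col-0, the 12 largest increases and 12 largest decreases among called probe sets of 1 gene whose 3 mutant arrays all lay on the same side of the 3 Col-0 arrays, and 4 per direction in the other contrasts. After the identifiers were checked, the condition on the gene was dropped and at most the 2 largest changes per direction are described, by their values and without identifiers.

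The samples entered a model without a block because the numbers in the labels were not known to pair them. The runs taken from the instrument records later showed that a number marks a shared hybridization run, so the replicate block and the run block are the same fit. Among 18 same-number pairs of arrays, the correlations of deviations from group means lay between -0.07 and 0.08. Comparisons, settings and most alternatives were fixed before the data were examined. The alternatives changed the filter, pseudocount, normalization, variance model, arrays in the fit, block, test and fold minimum, and left out each array in turn. Directions in a run were read for probe sets called without that run, a check chosen after the calls had been seen.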

Results

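The 12 arrays measured transcript levels in rosettes of Col-0, pmr5, pmr6 and pmr5 pmr6, with 3 arrays per genotype. The series title presents pmr5 and pmr6 as mutants of the plant cell wall. Both were isolated as powdery mildew resistant, and PMR6 encodes a pectate lyase-like protein. The comparisons ask how transcript levels change with each mutation and whether the changes of the double mutant equal the sum of those of the single mutants. Arrays correlated with each other at Spearman coefficients between 0.937 and 0.973 over all rows.

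The identifiers attached to the rows did not track the values. Over 139 pairs of rows assigned to the same gene, mean log2 levels correlated at r = 0.08 (95% interval -0.09 to 0.24; one-sided permutation p = 0.17). Profiles across the 12 arrays correlated at a mean of 0.02 (one-sided permutation p = 0.54). The row assigned to rbcL, which encodes the large subunit of Rubisco and is among the most abundant leaf transcripts, had a mean intensity of 32.8, at percentile 22.6 of all rows. The row assigned to psbA, a photosystem II gene of the plastid, stood at percentile 59. As a set, the rows assigned to 43 plastid photosynthesis genes had a median intensity of 238.6 against 180.3 for all rows, at percentile 78.4 of 10000 random lists. Whether the labelling captured plastid transcripts in proportion to their abundance was not tested, so these levels are weak evidence on the identifiers. Rows with identifiers of 9 hybridization spike-in controls had mean intensities of at most 139.5, and their profiles correlated at a mean of -0.02. The first 9 rows of the table, whose identifiers are not those of controls, correlated at a mean of 0.94, against at most 0.62 in 10000 random runs of 9 rows drawn after the first 64. Rows are therefore reported as probe sets of unknown identity, and no gene is named.

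**Figure D1:**
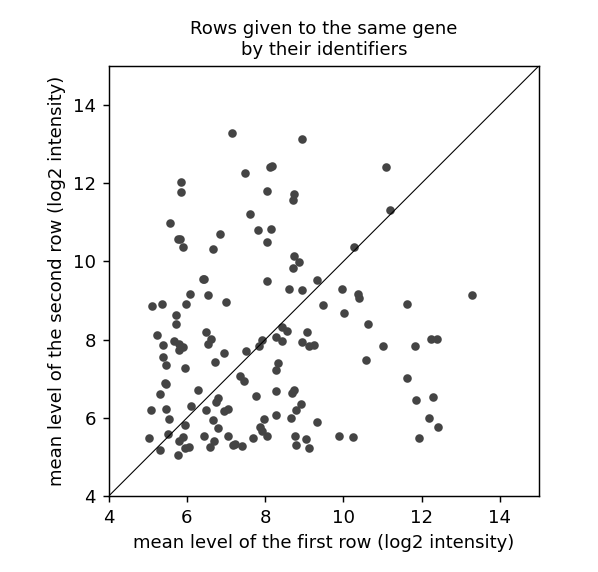
Mean log2 intensity over 12 arrays of 139 pairs of rows whose identifiers are assigned to the same gene, first row on the x axis and second row on the y axis; the line marks equality. The points do not follow the line, with r = 0.08.

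The genotypes were ordered along the first principal component, which held 27.8% of the variance. Col-0 lay at -27.9 ± 4.9, pmr6 at -5 ± 1.6, pmr5 at 4.3 ± 5.9 and pmr5 pmr6 at 28.6 ± 3.8 (mean ± SD, n = 3 each). The second component held 12.5% and set apart pmr5 pmr6 replicate 3, at 32.9. That array had the lowest mean correlation with the others (Spearman 0.947) and, with pmr5 replicate 1, a raised dim end, with 5th percentiles of 9.2 and 9.6 against 3 to 5 on the other arrays.

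**Figure D2:**
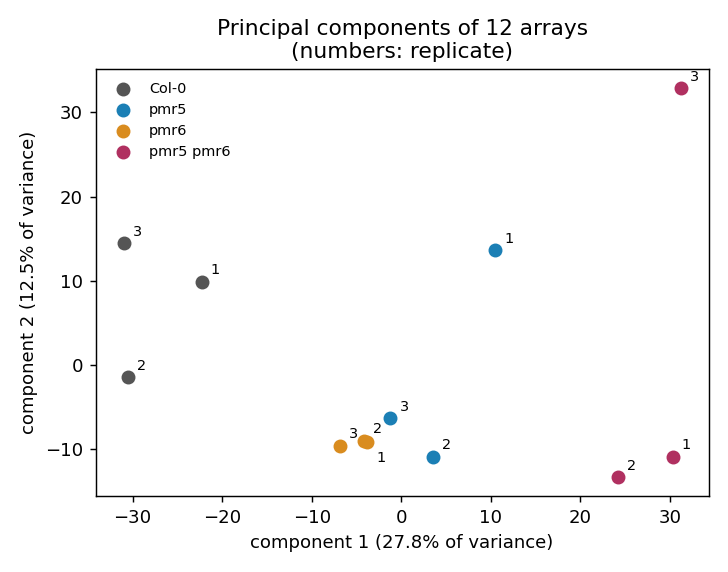
Scores of the 12 arrays on the first (x axis, 27.8% of variance) and second (y axis, 12.5%) principal components of log2 intensity, coloured by genotype and numbered by replicate. Col-0 and pmr5 pmr6 lie at opposite ends of the first component and both single mutants between them.

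In pmr5, 1378 of 17059 probe sets differed from Col-0 (limma, adjusted p under 0.05), of which 715 were higher and 663 lower. The median change among them was 1.51-fold upward and 1.33-fold downward, and 191 changed at least 2-fold, 164 upward and 27 downward. The largest increase was 7.17-fold, from an intensity of 171 ± 41.2 in Col-0 to 1386.5 ± 162.2 in pmr5 (SD, n = 3 each; log2 2.84, SE 0.18, limma adjusted p = 1.3e-08). The same probe set stood at 160.5 ± 47.3 in pmr6 and 360.9 ± 72.5 in pmr5 pmr6. Of the probe sets called when hybridization run 1, 2 or 3 was left out, 96.5%, 89.5% and 94.3% changed in the same direction in that run. With the run as a block 1462 were called. The count was 784 without pmr5 replicate 1, 902 without Col-0 replicate 3, 886 without both arrays that stood apart, 645 without the variance trend and 25 with an unmoderated 2-sample test.

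In pmr6, 579 probe sets differed from Col-0 by the same test, 366 higher and 213 lower, with 112 changed at least 2-fold (102 upward and 10 downward). The largest increase was 5.14-fold, from 236.3 ± 85.9 in Col-0 to 1329.7 ± 497.8 in pmr6 (SD, n = 3 each; log2 2.36, SE 0.23, limma adjusted p = 3.0e-06). In pmr5 and pmr5 pmr6 it stood at 442 ± 103.7 and 2374.7 ± 370.8. Of those called without run 1, 2 or 3, 92.9%, 95.8% and 97.4% had the same direction in that run, and 637 were called with the run as a block. The count was 358 without Col-0 replicate 3, 369 without pmr6 replicate 1, 337 without pmr6 replicate 2, 211 without the variance trend and 0 with the unmoderated 2-sample test, which gave 2130 probe sets an unadjusted p under 0.05.

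In pmr5 pmr6, 3285 probe sets differed from Col-0, 1685 higher and 1600 lower, with 565 changed at least 2-fold (450 upward and 115 downward). The probe set with the largest increase rose from 113.1 ± 21.2 to 1895.7 ± 612.1 (log2 3.72, SE 0.21, limma adjusted p = 2.3e-10), and stood at 387.9 ± 85.5 in pmr5 and 605.4 ± 126 in pmr6. The next largest increase was from 109.7 ± 110.4 to 1104.1 ± 327.9 (log2 3.37, SE 0.4, limma adjusted p = 2.4e-06), with log2 2.68 without Col-0 replicate 3 and 4.01 without Col-0 replicate 1. The largest decrease was from 1028.8 ± 110.7 to 203 ± 32.4 (log2 -2.2, SE 0.13, limma adjusted p = 3.6e-10), with 403.9 ± 46 in pmr5 and 566 ± 22.1 in pmr6. The next largest decrease was from 707.3 ± 87.5 to 172.1 ± 89.7 (log2 -1.98, SE 0.24, limma adjusted p = 2.7e-06), while pmr5 and pmr6 stood at 680.6 ± 123.9 and 629 ± 136.8 (SD, n = 3 each). Of those called without run 1, 2 or 3, 94.8%, 97.4% and 93.8% had the same direction in that run, and 3352 were called with the run as a block. The unmoderated test called 1019.

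**Figure D3:**
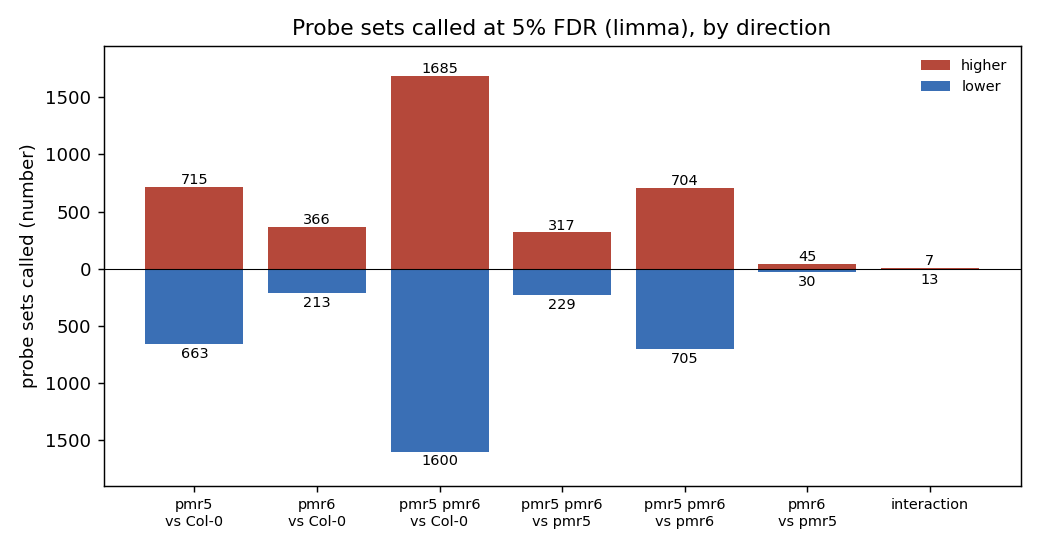
Number of probe sets called at an adjusted p under 0.05 in each of 7 contrasts, with those higher above 0 and those lower below 0. The double mutant against Col-0 has the tallest bars, 1685 higher and 1600 lower, and the interaction the shortest, 7 and 13.

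The changes of pmr5 and pmr6 overlapped. Both called the same 255 probe sets higher and 169 lower, against 15.3 and 8.3 for independent lists, and none in opposite directions. In 100 simulations of unchanged mutants against newly drawn Col-0 arrays, 0 calls were shared. That value leaves little to compare, since unchanged mutants give few calls to share. The deviations of the real Col-0 arrays did not enter these simulations. Across probe sets, which are not independent replicates, the log2 changes correlated at r = 0.68, against 0.5 in simulations of unchanged mutants. The covariance was 0.062 against a simulated 0.0252, a difference of 0.0368. Since 3 Col-0 arrays cannot be divided into parts of at least 2, part of the excess overlap may come from the shared controls. Of the probe sets called in pmr5, 643 of 715 higher and 594 of 663 lower were called in the same direction in pmr5 pmr6, where independent lists would share 70.6 and 62.2. Of those called in pmr6, 339 of 366 higher and 194 of 213 lower were, against 36.2 and 20. These lists share the Col-0 arrays too: the same simulations shared 0 calls where 1237 (pmr5) and 533 (pmr6) were observed, with the same limit, so part of that overlap may come from the controls as well. Another 1929 were called in the double mutant and in neither single mutant, which alone does not show that they differ from the single mutants.

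Each mutation was also compared in 2 backgrounds that share no arrays. The pmr5 effect in Col-0 and in pmr6 correlated at r = 0.41 across probe sets, with the same sign in 63.9%. Within the 3 runs r was 0.2, 0.29 and 0.11. Each run had 1 array per genotype, and the added noise lowers r. The covariance of the effect was 0.0406, 0.0484 and 0.0237 within the runs, against 0.0411 over the group means. Against pmr6, 1409 probe sets differed in pmr5 pmr6, 704 higher and 705 lower. Of these, 342 higher and 320 lower were also called in pmr5 against Col-0, where independent lists would share 29.5 and 27.4. The pmr6 effect in Col-0 and in pmr5 correlated at r = 0.27, with the same sign in 57.3%, and at 0.13, 0.2 and 0.07 within the runs. Its covariance was 0.0245, 0.0294 and 0.0145 within the runs, against 0.0222 over the group means. Against pmr5, 546 probe sets differed in pmr5 pmr6, 317 higher and 229 lower, and 158 and 55 of them were shared with pmr6 against Col-0, against 6.8 and 2.9 for independent lists. All lists came from 1 fit with a shared spread per probe set, and each held the most calls among the brightest probe sets. Independent lists are therefore a low baseline, here and for the overlaps above. The count of 1409 was 773 without pmr6 replicate 3 and 818 and 939 without pmr5 pmr6 replicate 1 or 2, and that of 546 was 270 without pmr5 replicate 3, 263 without pmr5 pmr6 replicate 1 and 341 without pmr5 pmr6 replicate 2. With the run as a block the counts were 1475 and 612, and without the variance trend 677 and 140. The unmoderated 2-sample test called 8 and 0, with 3090 and 1956 at an unadjusted p under 0.05. The correlations depended on the dim filter: for pmr5 and pmr6 they were 0.28 and 0.17 without it and 0.61 and 0.48 with the dimmest 50% left out.

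**Figure D4:**
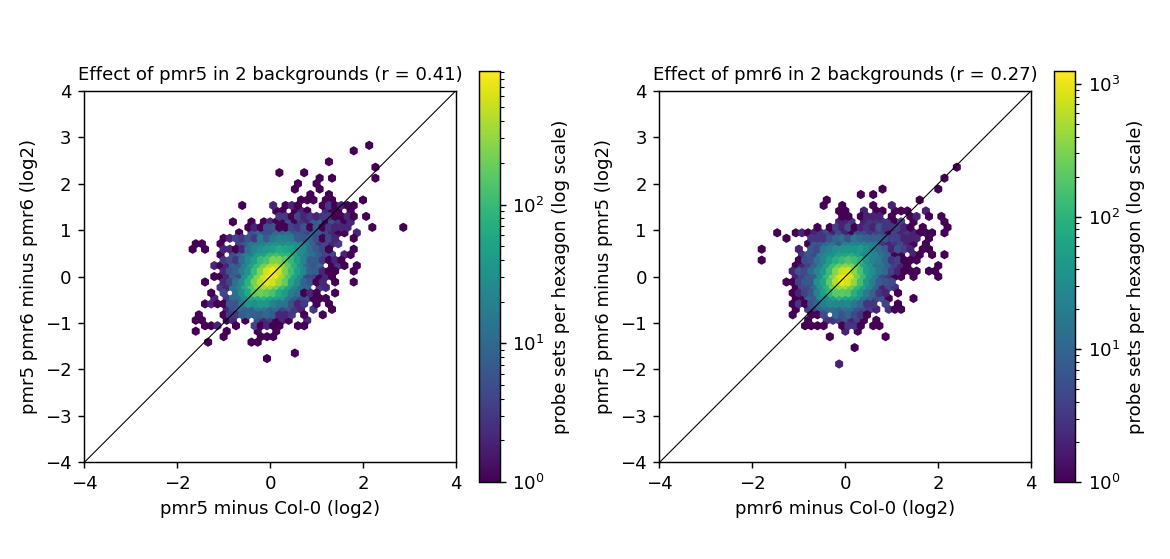
Log2 change of each probe set with the pmr5 mutation in Col-0 (x axis) and in pmr6 (y axis), left, and with the pmr6 mutation in Col-0 (x axis) and in pmr5 (y axis), right; colour gives the number of probe sets per hexagon on a log scale and the line marks equality. The effects correlate at r = 0.41 and r = 0.27 (0.28 and 0.17 without the dim filter).

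Between the single mutants, 75 probe sets differed, 45 higher and 30 lower in pmr6. The largest difference was the probe set with the largest increase in pmr5, 7.63-fold lower in pmr6 (log2 -2.93, SE 0.18, limma adjusted p = 1.1e-08). With the run as a block 113 were called, 54 higher and 59 lower. The count was 15 without pmr5 replicate 1, 192 without pmr5 replicate 2, 42 without pmr5 replicate 3, 29 without pmr6 replicate 2, 19 without pmr6 replicate 3, 46 without pmr5 pmr6 replicate 2, and 16 without both arrays that stood apart. It was 42 with no dim filter, 6 without the variance trend and 0 with the unmoderated 2-sample test, which gave 1688 an unadjusted p under 0.05.

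For 20 probe sets the double mutant departed from the sum of the single-mutant log2 changes, 7 above it and 13 below. For 1 of the 7, with the largest departure upward (log2 2.31), the sum was 4.61 on the log2 scale, below the 4.81 that an intensity of 0 gives, so part of that departure was fixed by the scale. The next largest upward was log2 0.96 (SE 0.18, limma adjusted p = 0.039): the intensity was 1565 ± 290.8 in Col-0, 1399.1 ± 171.4 in pmr5, 1340.8 ± 184.2 in pmr6 and 2367.6 ± 336 in pmr5 pmr6 (SD, n = 3 each). The largest departure downward was log2 -1.9 (SE 0.33, limma adjusted p = 0.027). There Col-0 stood at 853.6 ± 216.8, pmr5 at 3060.2 ± 1241.1, pmr6 at 3419.4 ± 448.7 and pmr5 pmr6 at 3092.8 ± 663.5. The run as a block gave 26. The count was 33 without Col-0 replicate 2 and between 3 and 8 without Col-0 replicate 3, pmr5 replicate 1, pmr6 replicate 2 or 3, or pmr5 pmr6 replicate 1 or 3, and 6 without both arrays that stood apart. It was 12 with the robust trend, 3 with no dim filter and 1 without the variance trend, and in the last 2 settings all calls lay below the sum. The median SE of an interaction was 0.22 on the log2 scale, against 0.15 for a comparison of 2 genotypes.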

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

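The tests of the row identifiers, of the fluidics modules and of the place of pmr5 pmr6 replicate 3 between the genotypes were chosen after the values they bear on had been seen.

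The effect of pmr5 differed between the Col-0 and pmr6 backgrounds for 20 probe sets by the limma interaction test. When residuals of the additive model were reordered over the arrays, 1 of 100 orders, the real one, gave as many, and the highest other gave 16. Chance is therefore an unlikely source of the count in the main setting. No reordering was made in the other settings, so chance was not tested there. The same count fell to 6 without both arrays that stood apart and to 1 without the variance trend.

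Of the 64 rows with AFFX identifiers, which the tests left out as controls, 4 differed in a comparison with Col-0 when fitted with all rows in limma (adjusted p under 0.05). Among the 22746 other rows, fitted with no dim filter, a larger share was called: 3080 in pmr5 pmr6 against Col-0 alone. The row deposited as AFFX-DapX-5_at stood at 348 ± 56 in Col-0 (SD, n = 3) and at 204.7 in pmr5, 196.9 in pmr6 and 200.2 in pmr5 pmr6. The other called rows passed in pmr5 pmr6 only. Among them AFFX-r2-Ec-bioC-3_at was higher, at 39 in Col-0 and 96.8 in pmr5 pmr6, and the rest were lower. Since identifiers did not track values, these rows may not be controls, and controls may be among the 17059 probe sets tested. With the first 64 rows left out in place of the AFFX rows, an alternative added after seeing the data, the counts were 1393, 592 and 3287 for pmr5, pmr6 and pmr5 pmr6 against Col-0. They were 556 and 1426 for pmr5 pmr6 against pmr5 and pmr6, 77 for pmr6 against pmr5 and 21 for the interaction.

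The row identifiers did not track the values. Noisy measurements are argued against by the lowest Spearman correlation of any 2 arrays, 0.937. Probe sets of 1 gene that measure different transcripts are argued against by the rows with spike-in identifiers, whose profiles correlated at a mean of -0.02. Identifiers displaced from the values may explain it: the first 9 rows correlated at 0.94, as spike-in controls would, under other identifiers, and 10000 random runs of 9 rows from the whole table at no more than 0.73. No biological explanation was tested.

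The differences between genotypes follow the fluidics modules, since each genotype was run on 1 module only. An even trend over modules 1 to 4 would make the covariance of the pmr6 effect between backgrounds 4 times that of the pmr5 effect. The ratio was 0.54, and 0.6, 0.61 and 0.61 within the runs, which argues against such a trend as the whole cause. Other module offsets and the genotypes cannot be told apart.

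The array pmr5 pmr6 replicate 3 correlated least with the others. In the brighter 50% of the probe sets its mean correlation ranked 4 of 12, counted from the lowest, so uneven signal of dim probe sets is a candidate explanation. On an axis from Col-0 (0) to the double mutant (1) it lay at 0.748, above every array of another genotype by at least 0.136 against an SD of at most 0.08 within a genotype, which argues against a sample of another genotype of this series. That comparison was added after the place had missed a first bound of 0.75, and a sample from outside the series stays open. No biological explanation was tested.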

How the results depend on the processing

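The unmoderated test on 3 against 3 arrays called 25 probe sets for pmr5, 0 for pmr6 and 1019 for pmr5 pmr6 against Col-0, and 0, 8 and 0 for pmr5 pmr6 against pmr5, against pmr6, and pmr6 against pmr5. Where it called 0, 2130, 1956 and 1688 had an unadjusted p under 0.05. Without the variance trend the counts were 645 and 211 for pmr5 and pmr6 against Col-0, 140 and 677 for pmr5 pmr6 against pmr5 and pmr6, 6 for pmr6 against pmr5 and 1 for the interaction; the cause was not tested. A fold minimum of 2, which only removes calls, left 191, 112, 565, 76, 158, 10 and 9 in the order of the contrasts. With no dim filter pmr6 against pmr5 gave 42 and the interaction 3, and the robust trend gave 12 for the interaction. The replicate block, which is also the hybridization run, gave 113 for pmr6 against pmr5 and moved no other count by over 1.5 times; the numbers share runs, but no same-number pair correlated over 0.1. The correlation between backgrounds was 0.28 (pmr5) and 0.17 (pmr6) without a dim filter and 0.61 and 0.48 with the dimmest 50% left out, where the pmr5 and pmr6 changes correlated at 0.75. It was 0.51 and 0.37 with a pseudocount of 101, and 0.2 for pmr6 with a pseudocount of 4. Without both arrays that stood apart, an alternative chosen after seeing the data like the 2 on control rows, pmr5 against Col-0 gave 886, pmr6 against pmr5 16 and the interaction 6. In the order of the contrasts, 60.2%, 97.4%, 81.3%, 64.8%, 75.1%, 21.3% and 20% of the main calls were kept there in the same direction. The cause was not tested.

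Leaving out each array in turn gave 784 to 1460 for pmr5, 337 to 639 for pmr6 and 2619 to 3297 for pmr5 pmr6 against Col-0, 263 to 602 and 773 to 1494 for pmr5 pmr6 against pmr5 and pmr6, 15 to 192 for pmr6 against pmr5 and 3 to 33 for the interaction. The correlations ran from 0.62 to 0.73 for pmr5 and pmr6, and from 0.33 to 0.43 and 0.2 to 0.3 between backgrounds. The 4 probe sets given for the largest changes of pmr5 pmr6 against Col-0 kept their direction and side of the threshold in every alternative run on them. The unmoderated test and the fold minimum were not among these. Gene lists, named genes and the PMR5 and PMR6 transcripts were not run. Of the calls in pmr5, 63 were among the dimmest 4265 probe sets tested and 766 among the brightest. In simulated data for pmr5 against Col-0 on 17059 probe sets, 200 of each intensity level were changed by 1 log2. Recovery was 39% among the dimmest and 98.5% among the brightest, so dim signal limited detection there.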

Other observations

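The tests of groupings were set before their results were seen. In a test of any difference among the 4 genotypes, limma called 2593 probe sets, and the highest of 99 other groupings of the 12 arrays gave 696. Only the real grouping, 1 of 100, reached that count, which makes chance an unlikely source of it. The other groupings were drawn without regard to the hybridization runs. For each of the 6 pairwise comparisons the 10 splits of 6 arrays are too few for a share under 0.05. The real splits gave 1378, 579, 3285, 546, 1409 and 75 probe sets, and the highest other split gave 0 in each, with 446 to 1468 probe sets at an unadjusted limma p under 0.05 over the 54 other splits. Every other split mixed arrays of both genotypes within its groups. A difference between the genotypes then widens the spread and lowers the calls, so these counts of 0 do not measure chance alone.

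Of the probe sets called in pmr5 pmr6 against Col-0, 415 were called in the same direction in both single mutants. These comparisons share the Col-0 arrays, so part of that count may come from the controls. After correction for noise, the slopes of the pmr5 effect in pmr6 on that in Col-0, and the reverse, were 0.83 and 0.8. Those of the pmr6 effect were 0.71 and 0.7. The correction used 1 mean noise variance for all probe sets, in the main setting only. Slopes under 1 in both directions do not show that an effect was weaker in a given background.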
